A study of Caenorhabditis elegans with 24 samples.

How the data were processed

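Messenger RNA sequencing (mRNA-seq) and ribosome profiling, which sequences the mRNA stretches covered by ribosomes (footprints), were carried out on adult Caenorhabditis elegans. Per the labels, the animals were wild type (WT) or carried a deletion of C38D4.9, the gene named metl-5, and had been kept at 20 or 37 °C. Each of the 8 groups of assay, strain and temperature held 3 libraries, 24 in all. The duration of the 37 °C exposure and the extraction and library protocols are not given in the sources used here. Nothing tells whether replicates came from separate cultures of worms, so the p-values measure the spread between these samples only, which may be technical.

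The authors deposited raw counts of reads per gene for each library. The deposited count files have the layout of STAR gene counts, and STAR and DESeq2 are named, without versions, in the submitters' processing notes. Aligner options, the genome build and the annotation are not given in the sources used here. The files list 19669 genes, of which 19332 were paired with a symbol and 19568 were found in the WBcel235 annotation (Ensembl), which gave the places of genes printed here. Each count file gives reads without regard to strand and on either strand. In the mRNA libraries 50.5 to 50.9% of the stranded counts lay on the gene's strand, so the unstranded counts were used. An mRNA read over 2 genes on opposite strands therefore cannot be told apart. In the footprint libraries 99.7 to 99.9% lay on the gene's strand, and the sense-strand counts were used. Reads that were unmapped, mapped to several places or fell in no gene or in several made up 19.5 to 27.1% of the reads of an mRNA library and 14.8 to 52.1% of those of a footprint library, and were left out.

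The authors also deposited 6 tables of their own comparisons of mutant with WT, with log2 fold changes, p-values and adjusted p-values under DESeq2's column names, per the file headers. These deposited tables also hold a base mean, a signal averaged over normalized libraries by the authors. The base means of the footprint tables followed the mean of unstranded counts over 10 libraries, without metl-5 20 °C replicate 2 and WT 37 °C replicate 2, with a median difference of 6.86e-09%. Against all 12 libraries the median difference was 4.07%. The fold changes of the authors' combined mRNA table followed the strain by temperature interaction computed here, with a correlation of 0.999 across genes. No value of these tables entered a test, but their base means decided which 2 footprint libraries were left out in some later fits.

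Genes with few counts were removed with filterByExpr, libraries were scaled with TMM, and the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) was run with all libraries of an assay in one fit and Benjamini-Hochberg adjustment at 0.05. In each assay the mutant was compared with WT at 20 °C, at 37 °C and averaged over both temperatures, 37 °C with 20 °C within each strain, and the strain effects at the 2 temperatures with each other (the interaction). Translational efficiency, the footprint level of a gene relative to its mRNA level, was tested in one edgeR count model over all 24 libraries as the interaction of assay with strain or temperature. The tests covered 13315 genes for mRNA, 12387 for footprints and 12079 for translational efficiency. Levels are counts per 1000000 gene counts of a library (CPM), given as mean ± SD, and fold changes are log2 values ± SE. Every fold change is relative to the other transcripts of a library, since no added standard is given.

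The tests, their design, 32 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 31 lists that had at least 3 tested members. They matched 1827 members, and 45 names were not matched. Counts of changed members are given over all genes tested and adjusted over the list alone. The rule took metl-5 and the cytochrome P450 gene cyp-29A3 in every comparison. It added the 8 genes with the largest rises and the 8 with the largest falls among called genes that have a symbol, a mean log2 CPM of at least 1 and no overlap between the libraries compared, and up to 3 members with the smallest p of each list that camera called. Other genes named are said to have been chosen after their values were seen.

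On simulated counts with the real means and library sizes and 100 genes changed by each fold size, edgeR recovered 63% of 4-fold and 8% of 2-fold changes in the mRNA comparison of strains at 20 °C (13315 genes). In the footprint comparison of strains at 20 °C (12387 genes) it recovered 74% and 4%. For translational efficiency at 20 °C (12079 genes) it recovered 23% and 1%. The simulated libraries were independent, without pairing or reads of another group, and 200 genes were changed in each simulation. These shares may therefore overstate what could be recovered in the real libraries.

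The alternatives were DESeq2 size factors within edgeR, the Wald test of DESeq2 1.42.0, no filter on low counts, the replicate number as a block (for translational efficiency, the pair of mRNA and footprint library), only the compared groups in the fit, limma on paired differences for translational efficiency, camera with an estimated correlation, and leaving out each library. Added after seeing the data were fits without the 2 footprint libraries absent from the authors' tables, fits without 6 doubted footprint libraries, and unstranded footprint counts. Pairing was checked from the deviations of same-numbered libraries from their group means. The correlation of every pair was over 0.1 for mRNA between strains (0.15 to 0.51 at 20 °C, 0.22 to 0.49 at 37 °C), for footprints between strains (0.32 to 0.56 and 0.31 to 0.60), for footprints between temperatures (0.21 to 0.51 in WT, 0.16 to 0.30 in the mutant) and for mRNA with footprints of a group (0.13 to 0.65). There the numbers were taken to pair the libraries. For mRNA between temperatures they do not (−0.03 to 0.40 in WT, 0.01 to 0.23 in the mutant).

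Replicates of a group differed by more than counting noise (chi-square per degree of freedom 27.7 to 118 for mRNA and 23.3 to 141 for footprints), so none was treated as a repeated library. Depth limits low genes: 3 counts, the upper limit that a count of 0 allows, equal 0.174 to 0.193 CPM in the mRNA libraries and 0.158 to 0.680 CPM in the footprint libraries. Such limits and counting intervals cover counting error only. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the tables and plots.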

Results

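Adult worms of 2 strains, wild type (WT) and a mutant lacking C38D4.9 (metl-5), were compared at 20 and 37 °C. METL-5 is known as a methyltransferase that places N6-methyladenosine on ribosomal RNA, and 37 °C is a strong heat stress for C. elegans, which is usually kept near 20 °C. The mRNA level and the ribosome footprints of every gene were counted in 3 libraries per strain, temperature and assay. Each mRNA library held 15522050 to 17239906 gene counts. Footprint libraries were deeper at 20 °C (11503305 to 19012050) than at 37 °C (4410194 to 10947947), and in WT 37 °C replicate 1 of the footprints 34.8% of all reads were unmapped.

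The first question was whether the deleted gene was lower in each library of the mutant. The gene metl-5 (WBGene00008008; WBcel235 chromosome III, 4803007 to 4804753, plus strand) had an mRNA level of 8.89 ± 2.07 CPM in WT at 20 °C (SD, n = 3) and 2.31 ± 0.271 in the mutant. At 37 °C the levels were 7.33 ± 1.14 and 2.86 ± 0.515 CPM. Each WT mRNA library held 106 to 164 metl-5 counts and each mutant library 36 to 56, so the mRNA libraries followed their labels with reads left in the mutant. The gene overlaps pal-1 on the opposite strand, and unstranded mRNA reads of these genes cannot be told apart. Footprints on metl-5 were at 5.84 ± 1.21 CPM in WT and 1.44 ± 0.906 in the mutant at 20 °C. At 37 °C they were at 7.07 ± 1.43 in WT, but the 3 libraries labelled mutant held 1.29, 7.85 and 5.35 CPM. Replicate 2 thus lay in the WT range of 5.56 to 8.40 CPM, and replicate 3 just below it.

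A further 3 genes marked the strains, chosen after their values were seen. ZK228.3 (chromosome V, 18458241 to 18461250) and ZK228.4 (V, 18462787 to 18465426) had 996 and 593 mRNA counts over the WT libraries at 20 °C and 0 in the mutant. cTel55X.1 (chromosome X, 17714961 to 17718726) had 618 mRNA counts in the mutant and 0 in WT. Among the 12 mRNA libraries 0 held at least 10 counts of a marker of the other strain. Among the 12 footprint libraries 4 held markers of both strains. WT 20 °C replicate 2 had 147 cTel55X.1 footprint counts, 69.4% of the mean level in mutant 20 °C replicates 1 and 3. WT 37 °C replicate 3 had 27 cTel55X.1 counts (42.2% of the level in mutant 37 °C replicate 1). The library labelled metl-5 37 °C replicate 2 had 63 ZK228.3 and 96 ZK228.4 counts (33.2 and 78.4% of the level in WT 37 °C replicate 1), and replicate 3 had 57 and 30 (40.2 and 32.8%).

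A further pair of footprint libraries stood between the temperatures and were the libraries absent from the authors' deposited footprint tables. In metl-5 20 °C replicate 2, hsp-70 footprints were at 5083 CPM, against 25.5 and 10.8 CPM in the other mutant libraries at 20 °C. In WT 37 °C replicate 2 they were at 6909 CPM, against 17602 and 24087 CPM. These 2 and the 4 libraries with markers of both strains are called the 6 doubted footprint libraries, which leaves 4 footprint libraries at 20 °C and 2 at 37 °C.

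**Figure D1:**
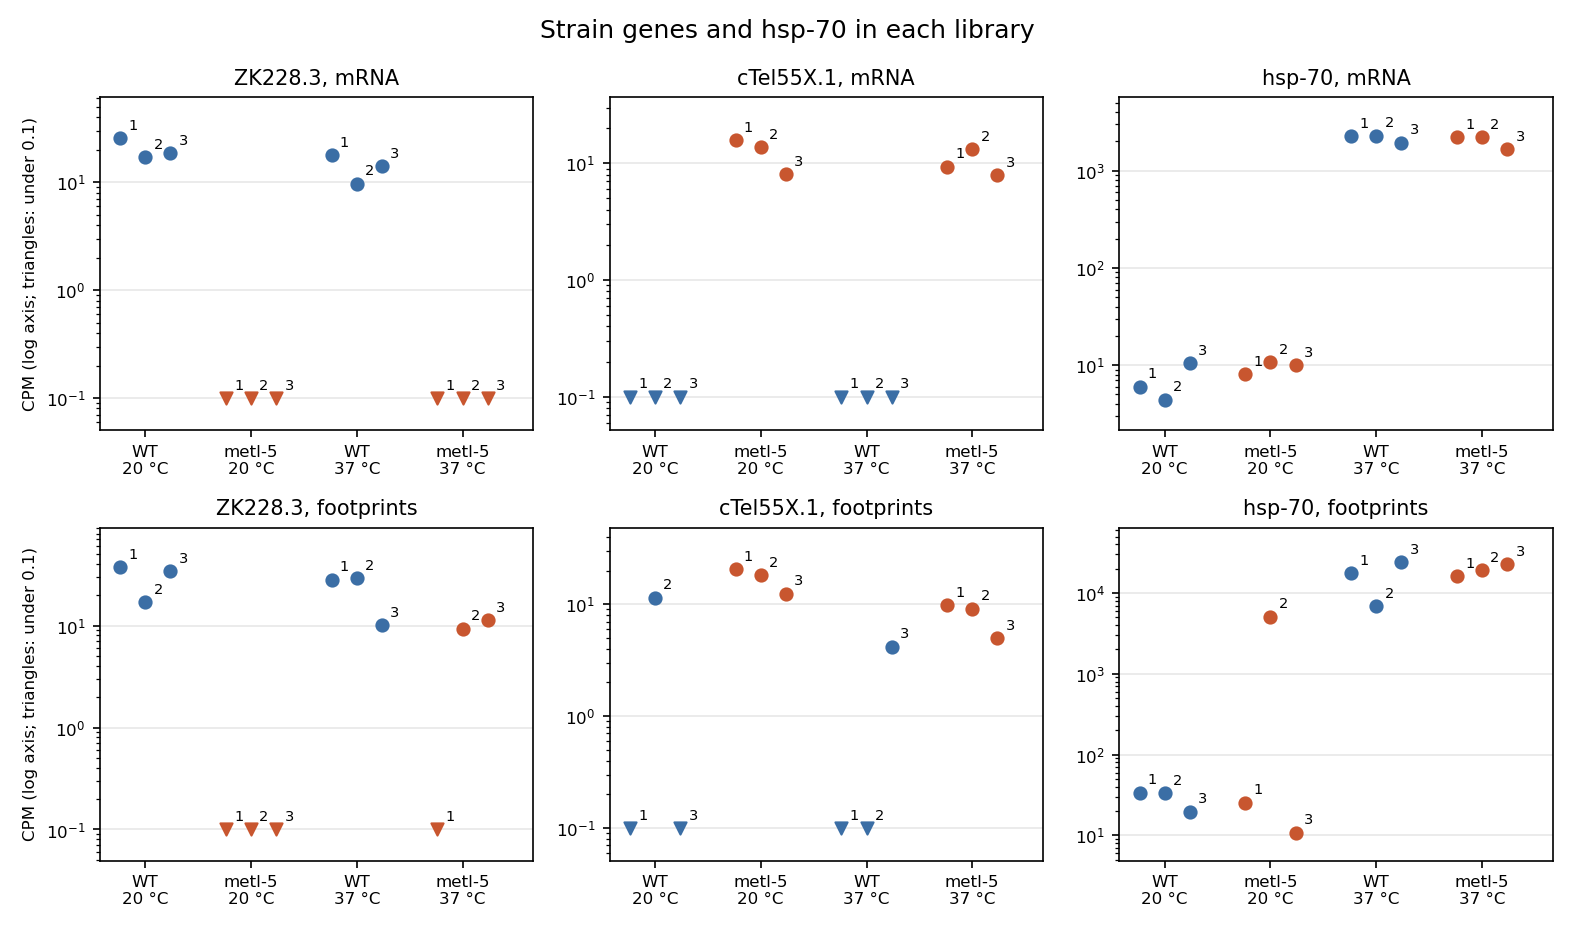
Level in CPM (log axis; triangles mark values under 0.1) of strain markers and hsp-70 in every library of each group, with 1 point per library. Each mRNA library shows the markers of its own strain, while 4 footprint libraries show those of both, and hsp-70 footprints in metl-5 20 °C replicate 2 reach 5083 CPM.

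The comparison of strains asks which mRNAs depend on metl-5. At 20 °C, 4 of 13315 genes were called (1 higher, 3 lower in the mutant). The unadjusted p was under 0.05 for 153 genes here and for 233 at 37 °C. Both are below the share of 0.05 that would be found without any difference, so the test may be too strict. ZK228.3 mRNA was at least 336.5-fold lower and ZK228.4 at least 200.4-fold lower in the mutant, and cTel55X.1 at least 203.2-fold higher, each against a floor of 3 counts over the group. F56A4.3 (V, 2453414 to 2456147) fell from 2974 counts to 6, a ratio of 502.4 (95% counting interval 230.8 to 1369). All 6 lay in mutant replicate 3, without which the log2 difference of F56A4.3 moved from −8.99 to −12.77. The adjusted p was 2.6e-05 for F56A4.3 and 5.09e-05 for the others. F56A4.3 was also chosen after its values were seen. The count rose to 8 genes with DESeq2 and to 8 with the replicate number as a block, which added cyp-29A3, metl-5, F42A9.6 (1.33, adjusted p = 0.0174) and col-93 (−1.21, 0.0174).

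At 37 °C the same 4 genes were called, with an adjusted p of 9.04e-05, and the replicate block added F42A9.6 (1.35, adjusted p = 0.0176). ZK228.3 was at least 224.6-fold and ZK228.4 at least 151.5-fold lower, and cTel55X.1 at least 164.9-fold higher. F56A4.3 fell from 1180 counts to 4, a ratio of 299.3 (116.9 to 1099). DESeq2 called 7 genes.

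The cytochrome P450 gene cyp-29A3 (WBGene00021412; V, 59239 to 63633) had 2.74 ± 0.264 CPM of mRNA in WT and 0.20 ± 0.144 in the mutant at 20 °C, and 6.31 ± 2.56 against 1.5 ± 0.633 at 37 °C (SD, n = 3). The log2 difference was −3.87 ± 0.646 at 20 °C (adjusted p = 0.0502) and −2.13 ± 0.541 at 37 °C (adjusted p = 1). For metl-5 mRNA it was −2.06 ± 0.394 (adjusted p = 0.139) and −1.38 ± 0.386 (adjusted p = 1). Averaged over temperatures both fell, cyp-29A3 by 3.00 ± 0.422 on the log2 scale (adjusted p = 0.00551) and metl-5 by 1.72 ± 0.275 (adjusted p = 0.0174), and both were lower in every mutant mRNA library than in any WT library of that temperature. At 20 °C both were called with the replicate number as a block, cyp-29A3 at −3.84 (adjusted p = 0.0229) and metl-5 at −2.07 (adjusted p = 0.0286), and with DESeq2 (5.52e-05 and 0.000297). In the authors' deposited table for 20 °C they stood at −3.92 (adjusted p = 0.000919) and −2.05 (adjusted p = 0.00146).

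**Figure D2:**
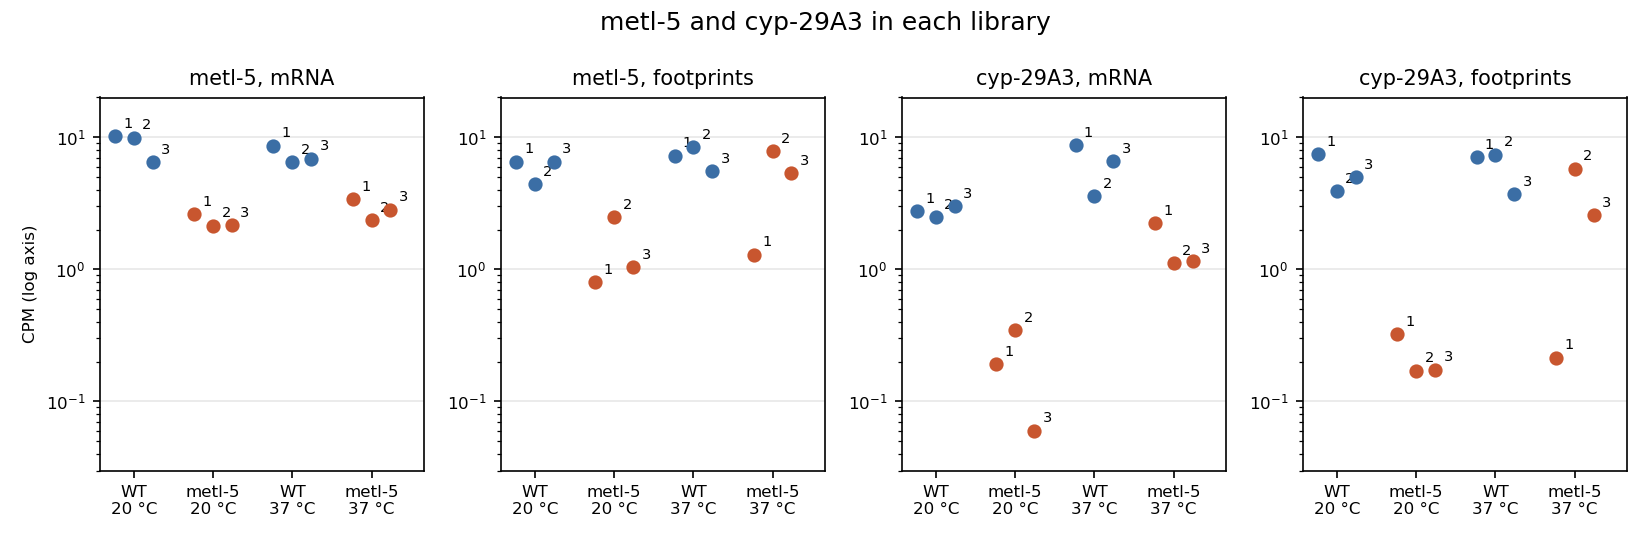
Level of metl-5 and cyp-29A3 in CPM (log axis) by assay, strain and temperature, with 1 point per library and the replicate number beside it. In mRNA every mutant library lies below the WT libraries of its temperature; at 37 °C the footprint libraries labelled mutant spread from 1.29 to 7.85 CPM for metl-5.

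The average over temperatures called 10 mRNAs (4 higher, 6 lower). Besides the 4 genes above, metl-5 and cyp-29A3, these were F42A9.6, T19E7.6 and hpo-15, which were higher, and R13H9.6, which was lower. All but hpo-15 were chosen after their values were seen. F42A9.6 rose by 1.35 ± 0.166 (adjusted p = 0.00117), from 32.3 ± 6.83 to 87.9 ± 11.1 CPM at 20 °C and from 20.7 ± 2.31 to 54.6 ± 15 at 37 °C, and T19E7.6 by 2.18 ± 0.335 (adjusted p = 0.0133). The rise of hpo-15 was 1.24 ± 0.197 (adjusted p = 0.0174) and the fall of R13H9.6 was −5.12 ± 0.849 (adjusted p = 0.0412). R13H9.6 had few mRNA counts, 8 to 14 per WT library at 20 °C and 13 to 19 at 37 °C. Mutant libraries held 1 to 2 at 20 °C and 0 at 37 °C, so the size of its fall is not well determined. F42A9.6 and hpo-15 each overlap a gene on the opposite strand (F42A9.17 and nhr-47), whose mRNA reads cannot be told apart. The count was 6 without WT 20 °C replicate 1. The call of R13H9.6 was lost in each of 12 fits that left out 1 library (adjusted p up to 0.273), without the filter (0.0576) and with the replicate block (0.117). The block also added col-93 (−1.01, adjusted p = 0.0026), nspa-5 (1.26, 0.0391) and T20F7.1 (1.65, 0.0291), named after their values were seen. That of metl-5 was lost in 9 of them (up to 0.104), that of hpo-15 in 8 (up to 0.104) and that of T19E7.6 without WT 20 °C replicate 1 or 3 (up to 0.0646).

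Among the gene lists, mRNAs of the 75 cytosolic ribosomal proteins leaned lower in the mutant at 20 °C. Their median log2 difference was −0.30 and 1 of 75 was positive, with 0 members called over all genes or adjusted over the list alone (camera adjusted p = 2.92e-19, adjusted p = 0.777 with an estimated correlation). The 143 cuticle collagens had medians of −0.43 at 20 °C (adjusted p = 6.02e-05, adjusted p = 0.953 with an estimated correlation) and −0.44 at 37 °C (3.39e-08, and adjusted p = 0.982 with an estimated correlation), with 0 members called. Single libraries decide the collagen values. At 20 °C the median was 0.23 without WT replicate 1, and without mutant replicate 2 the adjusted p was 0.0555. At 37 °C the median was −0.063 without WT replicate 1 (adjusted p = 0.899), and the call was also lost without mutant replicate 2. Of 31 lists camera called 10 at 20 °C (0 higher), 6 at 37 °C (2 higher) and 11 on average (3 higher), and with an estimated correlation 0 (adjusted p of at least 0.456).

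The same comparison for footprints asks which genes were occupied differently by ribosomes. Footprints on cyp-29A3 were at 5.44 ± 1.8 CPM in WT and 0.222 ± 0.0862 in the mutant at 20 °C (SD, n = 3), a log2 difference of −4.44 ± 0.761 (adjusted p = 0.269; −4.48 and 0.0329 with only the compared groups in the fit). For metl-5 the difference was −2.04 ± 0.53 (adjusted p = 1). At 37 °C the differences were −0.98 ± 0.631 for cyp-29A3 and −0.49 ± 0.515 for metl-5. There the mutant libraries held 1, 39 and 13 cyp-29A3 counts, the last 2 of them from the libraries that also held WT markers.

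With edgeR 0 of 12387 genes were called at 20 °C (86 at an unadjusted p under 0.05), 0 at 37 °C (238) and 0 averaged over temperatures (272). These unadjusted counts are below the share of 0.05 that would be found without any difference. The test may therefore be too strict, and counts of 0 do not exclude differences. DESeq2 called 3 genes at 20 °C (cyp-29A3 at −4.52 with an adjusted p of 3.22e-05, ZK228.3 and ZK228.4) and the same 3 averaged over temperatures, and 0 at 37 °C. Without the 6 doubted libraries edgeR called ZK228.3, ZK228.4 and cTel55X.1 at 20 °C, 3 genes at 37 °C (ZK228.3, gid-1 and mtd-1) and 4 averaged over temperatures, with cyp-29A3 at −4.68 (adjusted p = 0.044). The marker genes among these calls are no test, since 4 of the 6 libraries were chosen by those markers. At 37 °C that fit sets 1 library against 1, with a spread taken from the other groups, and the mutant library held 1 cyp-29A3 count. Without metl-5 37 °C replicate 1 alone edgeR called ZK228.3 and ZK228.4 on average. The genes gid-1 and mtd-1 were named after their values were seen. The authors' deposited footprint table for 20 °C, which follows 10 libraries, calls 4 genes, all lower: cyp-29A3 at −4.32 (adjusted p = 0.00353), metl-5 at −2.59 (0.0332), ZK228.3 (0.00353) and ZK228.4 (0.0077). The authors' deposited table for 37 °C calls 0.

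The heat shock chaperones differed between strains at 20 °C through 1 library. The log2 differences of the chaperone genes hsp-70, hsp-16.2 and hsp-16.41 were 5.80 ± 1.67, 6.06 ± 1.70 and 6.43 ± 1.77 (adjusted p = 1 for each). Without mutant replicate 2 they were −0.56, −0.61 and −0.42. For the list of 32 heat shock chaperones the median was 0.16 and the mean 1.1, with 0 members called over all genes and 3 adjusted over the list alone (camera adjusted p = 0.00011, adjusted p = 0.956 with an estimated correlation). Without mutant replicate 2 its call was lost (adjusted p = 0.676). The 130 cuticle collagens had a median of −0.38 with 0 called (1.53e-08, and adjusted p = 0.956 with an estimated correlation), and 0.145 without WT replicate 1. Its call was lost without the 2 libraries absent from the authors' tables (−0.197, adjusted p = 0.075). Of 31 lists camera called 8 at 20 °C (3 higher), 6 at 37 °C (2 higher) and 10 on average (4 higher) for footprints, and with an estimated correlation 0 (adjusted p of at least 0.956).

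Translational efficiency asks whether footprints moved apart from mRNA. For cyp-29A3 the mutant differed from WT by −0.61 ± 1.11 at 20 °C and 1.15 ± 0.847 at 37 °C, and for metl-5 by 0.91 ± 0.641 at 37 °C (adjusted p = 1 for each). The differences at 37 °C were −2.77 and −1.02 without the 6 doubted libraries. That fit keeps 1 mutant footprint library at 37 °C, which held 1 cyp-29A3 count, under the floor of 3 counts. With edgeR 0 of 12079 genes were called at 20 °C (48 at an unadjusted p under 0.05), 0 at 37 °C (164) and 0 averaged over temperatures (130). As for footprints, these unadjusted counts are below a share of 0.05, so the test may be too strict. DESeq2 called cTel55X.1 at 20 °C, cTel55X.1, ZK228.3 and ZK228.4 at 37 °C, and cTel55X.1 averaged over temperatures. With the library pair as a block cTel55X.1 was called at 20 °C and on average. Without footprint metl-5 37 °C replicate 1 edgeR called ZK228.3 and ZK228.4 at 37 °C. These marker calls say nothing on translation, since the ratio to mRNA has no value where a strain has 0 mRNA counts of the gene. The limma test on paired differences called ttm-2 at 37 °C, and ttm-2 and F56A4.3 on average. For 75 cytosolic ribosomal proteins, whose mRNA leaned lower, the median at 20 °C was 0.29 with 0 called (camera adjusted p = 4.29e-10, adjusted p = 0.988 with an estimated correlation), and the call was lost without mRNA mutant replicate 2 (0.12, adjusted p = 0.095). Of 31 lists camera called 7 at 20 °C (all higher), 1 at 37 °C (higher) and 6 on average (5 higher), and with an estimated correlation 0. The names of single genes come from the strain markers or were chosen after their values were seen. F56A4.3 had 6 and 4 mRNA counts in the mutant at the 2 temperatures, and 4 footprint libraries hold markers of both strains.

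Heat changed the mRNA of 2432 genes in WT (1300 higher, 1132 lower) and 2660 in the mutant (1440 higher, 1220 lower). The small chaperone mRNA hsp-16.2 rose by 10.23 ± 0.447 in WT and 9.61 ± 0.435 in the mutant (adjusted p = 1.58e-09 and 2.76e-09). The mRNA of hsp-70 rose by 8.75 ± 0.41 and 8.31 ± 0.402, from 6.99 ± 3.19 to 2164 ± 195.8 CPM in WT and from 9.61 ± 1.4 to 2027 ± 313.1 in the mutant (SD, n = 3). Among the mRNAs that fell were asp-13, an aspartyl protease gene (−4.97 ± 0.383 in WT, −4.26 ± 0.367 in the mutant), elo-6, a fatty acid elongase gene (−3.65 ± 0.313 and −3.78 ± 0.315), and the heme transporter gene hrg-4 (−3.28 ± 0.41 and −3.46 ± 0.414). Of the called genes 1051 were higher in both strains and 854 lower in both, where independent lists would share 140.6 and 103.7, and 0 were called in opposite directions. The lists of the strains are not independent. Same-numbered mRNA libraries of the strains deviated together and both comparisons share one fit, which could raise this overlap. The log2 changes in the strains correlated with r = 0.851 across genes, which are not independent replicates. For cyp-29A3 heat gave 1.75 ± 0.527 in WT (adjusted p = 0.0312, lost in 5 of 6 fits without 1 library) and 3.49 ± 0.651 in the mutant (adjusted p = 0.00213). For metl-5 it gave 0.24 ± 0.373 and 0.91 ± 0.392, neither of which was called.

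Of 36 heat shock chaperones 31 were higher in WT and 30 in the mutant, with 0 lower (32 and 32 higher, 0 and 1 lower adjusted over the list alone). Their medians were 1.68 and 1.67 (camera adjusted p = 3.29e-30 and 2.68e-28). This call held with an estimated correlation (adjusted p = 0.000869 and 0.0016), and no other list below did. Among 22 genes of the endoplasmic reticulum unfolded protein response 11 were higher in each strain and 2 and 4 lower (11 and 11 higher, 5 and 5 lower adjusted over the list alone; 0.0029 and 0.0095, adjusted p = 0.472 and 0.425 with an estimated correlation). The BiP gene hsp-4 rose by 3.39 ± 0.272 in WT and 3.32 ± 0.271 in the mutant, and the transcription factor gene xbp-1 by 1.70 ± 0.201 and 1.54 ± 0.20. Of 36 oxidative and xenobiotic stress genes 5 and 6 were higher and 1 and 0 lower (7 and 6 higher, 1 and 0 lower adjusted over the list alone; 0.0062 and 0.0036, adjusted p = 0.395 and 0.307 with an estimated correlation), with the glutathione S-transferase gene gst-1 up by 2.64 ± 0.213 and 2.73 ± 0.213.

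Cuticle collagen mRNAs rose together: 102 of 143 were higher in WT and 103 in the mutant, with 0 lower (83.9 and 83.2% higher, 1 and 0 lower adjusted over the list alone). The medians were 1.84 and 1.77 (5.16e-31 and 2.51e-27, adjusted p = 0.395 and 0.419 with an estimated correlation), with col-10 up by 3.13 ± 0.476 and 3.29 ± 0.48. Of 75 cytosolic ribosomal protein mRNAs 24 were higher in WT and 48 in the mutant, with 0 lower (34 and 60 higher adjusted over the list alone; 3.84e-12 and 4.02e-19, adjusted p = 0.573 and 0.425 with an estimated correlation). Of 48 translation factors 14 and 16 were higher and 2 and 2 lower (15 and 21 higher, 2 and 4 lower adjusted over the list alone; 0.000267 and 8.08e-05, adjusted p = 0.395 and 0.345 with an estimated correlation). The elongation factor gene eef-1A.1 rose by 1.38 ± 0.275 and 1.67 ± 0.277, and rps-8 by 1.31 ± 0.307 and 1.66 ± 0.31. Body wall muscle genes were higher in 16 and 17 of 31 cases with 0 lower (21 and 19 higher, 0 and 1 lower adjusted over the list alone; 9.84e-08 and 2.08e-07, adjusted p = 0.472 and 0.425 with an estimated correlation), among them the actinin gene atn-1 (1.23 ± 0.226 and 1.15 ± 0.226). Of 92 innate immunity genes 23 and 27 were higher and 3 and 6 lower (30 and 33 higher, 5 and 7 lower adjusted over the list alone; 8.62e-05 and 5.98e-05, adjusted p = 0.472 and 0.425 with an estimated correlation), with the antimicrobial peptide gene cnc-4 up by 2.32 ± 0.294 and 2.83 ± 0.302.

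In mRNA camera called the sperm and oocyte lists lower, and not the germline granule and meiosis list (adjusted p = 0.710 in WT and 0.987 in the mutant). Of 96 major sperm protein and spermatogenesis genes 26 were lower in WT and 19 in the mutant, and 3 were higher in each (33 and 19 lower, 3 and 3 higher adjusted over the list alone; 7.05e-07 and 6.3e-05, adjusted p = 0.677 and 0.763 with an estimated correlation). Of 31 oocyte and eggshell genes 6 and 4 were lower and 0 and 1 higher (10 and 4 lower, 0 higher adjusted over the list alone; 0.000189 and 0.0317, adjusted p = 0.630 and 0.836 with an estimated correlation). The oocyte maturation gene oma-1 fell by 1.31 ± 0.252 in WT and 1.28 ± 0.252 in the mutant. In the mutant the sperm list was no longer called without mutant 20 °C replicate 3 (adjusted p = 0.0947), nor the oocyte list without 20 °C replicate 2 or 37 °C replicate 1 or 3 (up to 0.0881). Leaving out 1 library gave 1175 to 2988 called genes in WT, with 1175 without 20 °C replicate 3 and 1193 and 1232 without 37 °C replicates 1 and 3. In the mutant it gave 1263 to 2509, with 1546, 1686 and 1735 without 20 °C replicates 1, 2 and 3 and 1542 and 1263 without 37 °C replicates 1 and 3.

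For footprints, heat called 2071 genes in WT (1212 higher, 859 lower) and 3332 in the mutant (1507 higher, 1825 lower). Footprints on hsp-16.41, hsp-16.2 and hsp-70 rose by 9.57 ± 2.016, 9.22 ± 1.946 and 9.05 ± 1.924 in WT (adjusted p between 0.0261 and 0.0263). In the mutant the fitted changes were 3.38 ± 1.522, 3.31 ± 1.482 and 3.54 ± 1.497 (adjusted p = 0.109, 0.107 and 0.0903), in a group that includes the 20 °C library with 5083 CPM of hsp-70. Without the 2 libraries absent from the authors' tables they rose by 10.252, 10.004 and 9.925 in the mutant (adjusted p = 4.6e-07, 4.6e-07 and 1.05e-06). These values in the mutant were chosen after they were seen. Of the called genes 1078 were higher and 775 lower in both strains, where independent lists would share 147 and 127, with r = 0.861 across genes. The 2 strains are not independent here, since 4 footprint libraries hold markers of both, and mixed reads could raise this overlap. For cyp-29A3 heat gave 0.06 ± 0.588 in WT and 3.52 ± 0.792 in the mutant (adjusted p = 0.951 and 0.0135). Without the 6 doubted libraries heat gave −0.449 in the mutant, from 1 footprint count at 37 °C. For metl-5 it gave 0.19 ± 0.495 and 1.74 ± 0.546 (adjusted p = 0.81 and 0.0345), and 0.31 in the mutant without them (adjusted p = 0.737).

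Of 32 heat shock chaperones 19 were higher in footprints in each strain and 0 lower (22 and 20 higher adjusted over the list alone; camera adjusted p = 8.75e-10 and 7.17e-09). With an estimated correlation no list was called from footprints (adjusted p = 0.707 in WT and 0.763 in the mutant for each list here). The myosin chaperone gene unc-45 rose by 1.55 ± 0.256 in WT and 1.54 ± 0.256 in the mutant, and the co-chaperone gene dnj-13 by 2.68 ± 0.463 and 2.38 ± 0.458. Of 36 germline granule and meiosis genes 8 and 12 were higher and 0 and 1 lower (15 and 13 higher, 0 and 1 lower adjusted over the list alone; 0.000197 and 0.000132, adjusted p = 0.707 and 0.763 with an estimated correlation), with the Notch receptor gene glp-1 up by 1.81 ± 0.326 and 1.85 ± 0.326. Of 31 body wall muscle genes 10 and 8 were higher and 0 and 1 lower (12 and 10 higher, 0 and 1 lower adjusted over the list alone; 0.0014 and 0.0031, adjusted p = 0.707 and 0.763 with an estimated correlation); in WT the call was lost without 37 °C replicate 1 (0.121).

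Camera called the collagens lower in footprints and higher in mRNA. Of 130, 41 had lower footprints in WT and 49 in the mutant, and 1 was higher in each (60 and 53 lower, 1 and 1 higher adjusted over the list alone). Their medians were −1.28 and −1.1 (3.02e-10 and 4.92e-07, adjusted p = 0.707 and 0.763 with an estimated correlation), with col-81 at −2.30 ± 0.517 and −2.85 ± 0.529. Of 75 cytosolic ribosomal proteins 6 were lower in WT and 22 in the mutant, with 0 higher (0 and 24 lower adjusted over the list alone; 1.75e-10 and 3.41e-08, adjusted p = 0.707 and 0.763 with an estimated correlation), with rla-0 at −1.28 ± 0.371 and −1.64 ± 0.375. Of 28 intestinal genes 8 and 14 were lower and 0 higher (17 and 17 lower adjusted over the list alone; 2.62e-07 and 3.51e-06, adjusted p = 0.707 and 0.763 with an estimated correlation), including the intestinal GATA factor gene elt-2 (−1.37 ± 0.312 and −1.81 ± 0.324). Of 46 UDP-glucuronosyltransferases 10 and 17 were lower with 0 higher (13 and 19 lower adjusted over the list alone; 5.67e-06 and 3.96e-06, adjusted p = 0.707 and 0.763 with an estimated correlation), and ugt-26 fell by 1.64 ± 0.379 and 2.59 ± 0.402. Of 37 fatty acid beta-oxidation genes 7 and 18 were lower and 0 and 1 higher (14 and 21 lower, 1 and 1 higher adjusted over the list alone; 0.000197 and 0.000108, adjusted p = 0.707 and 0.763 with an estimated correlation).

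Of 87 sperm genes 21 and 31 had lower footprints and 1 and 4 higher (42 and 35 lower, 3 and 4 higher adjusted over the list alone; 3.52e-09 and 2.85e-05, adjusted p = 0.707 and 0.763 with an estimated correlation). Of 47 nuclear genes of oxidative phosphorylation 5 and 10 were lower and 2 and 3 higher (4 and 11 lower, 1 and 3 higher adjusted over the list alone; 0.0065 and 0.0267, adjusted p = 0.707 and 0.763 with an estimated correlation); in the mutant the call was lost without 20 °C replicate 3 (0.113). Of 6 yolk protein genes 0 were called in WT and 5 were lower in the mutant (6 and 6 lower adjusted over the list alone; 0.00097 and 0.0024, adjusted p = 0.707 and 0.763 with an estimated correlation). The vitellogenin gene vit-5 stood at −1.63 ± 0.527 in WT (adjusted p = 0.0505) and −1.86 ± 0.531 in the mutant (0.025), and with the replicate block at −1.90 in WT (0.0276). The block also called vit-3 in WT (−1.89, 0.0301), and DESeq2 called both there (0.0132 and 0.0298). Without the 2 libraries absent from the authors' tables, one of which is WT 37 °C replicate 2, vit-5 and vit-3 stood at −2.71 and −2.69 in WT (0.000439 and 0.0013), and without the 6 doubted ones at −2.90 and −2.60 (0.0025 and 0.0035), so the strains are not shown to differ.

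These footprint calls rest on single libraries. In WT 0 genes were called without 20 °C replicate 1, 20 °C replicate 3, 37 °C replicate 1 or 37 °C replicate 3, 1042 without 20 °C replicate 2 and 4931 without 37 °C replicate 2. In the mutant 0 were called without 20 °C replicate 1, 289 without 20 °C replicate 3, 1149 without 37 °C replicate 1 and 695 without 37 °C replicate 3. It was 3113 without 20 °C replicate 2 and 3348 without 37 °C replicate 2. Each mutant call named here was thus lost without 20 °C replicate 1, in a fit that kept the doubted 20 °C replicate 2. With only the compared groups in the fit, WT had 118 calls (117 higher), and with the replicate block 3872. In the mutant these fits gave 4180 and 4896 calls. Without the 2 libraries absent from the authors' tables the mutant had 4240 calls, of which 3267 were shared with the 3332 of the main fit. Without the 2 libraries absent from the authors' tables WT had 4795 calls, of which 2057 were shared with the 2071, and without the 6 doubted libraries 2733 (1113 higher, 1620 lower).

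Set against mRNA, footprints changed with heat in 2335 genes in WT (1333 higher, 1002 lower) and 2528 in the mutant (1354 higher, 1174 lower). The germline sex determination gene fog-1 rose in translational efficiency by 3.76 ± 0.513 in WT and 3.58 ± 0.511 in the mutant, and aakg-5, a gene of an AMP-activated kinase subunit, by 3.72 ± 0.49 and 3.67 ± 0.489. The collagen genes col-146 and col-39 fell by 4.03 ± 0.603 and 4.09 ± 0.661 in WT and by 4.06 ± 0.609 and 4.08 ± 0.662 in the mutant. Adjusted p of these genes was between 0.000254 and 0.000631. Of the called genes 1144 were higher and 799 lower in both strains, where independent lists would share 149 and 97.4, with r = 0.807 across genes. This overlap has the same limit, since 4 of the footprint libraries hold markers of both strains. Neither cyp-29A3 (−1.66 ± 0.816 in WT, adjusted p = 0.164, and 0.10 ± 1.35 in the mutant, adjusted p = 0.971) nor metl-5 was called. The mutant value of cyp-29A3 turned to −3.837 without the 6 doubted libraries and to −0.463 with limma on paired differences. The first of these rests on 1 footprint library of the mutant at 37 °C with 1 cyp-29A3 count, under the floor of 3 counts.

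Of 130 collagens 95 fell in translational efficiency in WT and 87 in the mutant, and 1 and 0 rose (108 and 100 lower, 1 and 1 higher adjusted over the list alone). The medians were −3.01 and −2.92 (camera adjusted p = 4.92e-36 and 3.09e-29, adjusted p = 0.383 and 0.413 with an estimated correlation). Of 75 cytosolic ribosomal proteins 52 and 55 fell and 0 rose (61 and 65 lower adjusted over the list alone), with medians of −1.39 and −1.61 (2.37e-21 and 1.29e-25, adjusted p = 0.383 and 0.413 with an estimated correlation), and rps-8 at −2.37 ± 0.484 and −2.83 ± 0.487. Of 47 oxidative phosphorylation genes 15 and 19 fell and 1 and 1 rose (19 and 31 lower, 2 and 1 higher adjusted over the list alone; 1.32e-07 and 1.61e-09, adjusted p = 0.383 and 0.413 with an estimated correlation), with the cytochrome c1 gene cyc-1 at −2.1 ± 0.422 and −2.36 ± 0.423. Of 84 innate immunity genes 19 and 21 fell and 0 rose (22 and 21 lower adjusted over the list alone; 6e-07 and 1.98e-06, adjusted p = 0.423 and 0.473 with an estimated correlation), with spp-17 at −2.98 ± 0.55 and −3.27 ± 0.555. Of 28 intestinal genes 9 and 9 fell and 0 rose (10 and 12 lower adjusted over the list alone; 3.06e-06 and 9.77e-06, adjusted p = 0.423 and 0.473 with an estimated correlation), with the aspartyl protease gene asp-3 at −2.76 ± 0.606 and −2.69 ± 0.606. Of 6 yolk protein genes 3 and 4 fell and 0 rose (4 and 6 lower adjusted over the list alone; 0.000564 and 0.000268, adjusted p = 0.383 and 0.413 with an estimated correlation), vit-6 by 2.48 ± 0.666 and 2.58 ± 0.667.

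Camera called further lists lower. Of 32 heat shock chaperones 9 and 11 fell in translational efficiency and 1 and 2 rose (9 and 14 lower, 1 and 2 higher adjusted over the list alone; 0.0023 and 0.0063, adjusted p = 0.510 and 0.481 with an estimated correlation), with hsp-90 at −1.8 ± 0.321 and −1.78 ± 0.321. In the mutant that call was lost without footprint 20 °C replicate 2 (0.169), without the 2 libraries absent from the authors' tables (0.22) and without the 6 doubted ones (0.135). Of 22 unfolded protein response genes 8 and 8 fell and 3 and 3 rose (9 and 8 lower, 3 and 3 higher adjusted over the list alone; 0.0062 and 0.0083, adjusted p = 0.527 and 0.481 with an estimated correlation), with the calreticulin gene crt-1 at −2.2 ± 0.392 and −2.23 ± 0.392. Of 27 fatty acid synthesis and desaturation genes 8 and 7 fell and 0 and 2 rose (8 and 7 lower, 0 and 2 higher adjusted over the list alone; 0.0062 and 0.0029, adjusted p = 0.556 and 0.473 with an estimated correlation), among them the desaturase gene fat-6 (−2.25 ± 0.457 and −2.35 ± 0.457). Of 48 translation factors 12 and 13 fell and 0 and 3 rose (14 and 14 lower, 4 and 4 higher adjusted over the list alone; 0.0224 and 0.0127, adjusted p = 0.593 and 0.542 with an estimated correlation), with eef-1A.1 at −2.62 ± 0.553 and −3.25 ± 0.558.

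The ribosome biogenesis and germline lists were called higher in translational efficiency by camera, although few germline members were. Of 35 ribosome biogenesis genes 11 and 10 rose and 2 and 1 fell (11 and 11 higher, 2 and 1 lower adjusted over the list alone; 0.0071 and 0.0083, adjusted p = 0.617 and 0.634 with an estimated correlation), with pro-2 up by 1.96 ± 0.456 in each strain. Of 36 germline granule and meiosis genes 4 and 6 rose and 1 and 1 fell (4 and 6 higher, 0 and 1 lower adjusted over the list alone; 0.0025 and 0.0023, adjusted p = 0.617 and 0.626 with an estimated correlation), with glp-1 up by 2.57 ± 0.486 and 2.50 ± 0.485. Without footprint WT 37 °C replicate 3 the WT calls of the biogenesis, germline and fatty acid synthesis lists were lost (adjusted p = 0.0855, 0.0529 and 0.0535), and without mutant 37 °C replicate 3 the mutant call of the biogenesis list (0.0658). The WT call of the translation factors was lost without mRNA 20 °C replicate 1, mRNA 37 °C replicate 3 or footprint 20 °C replicate 3 (up to 0.128) and with only the compared groups (0.0546), and the mutant call without footprint 37 °C replicate 2 (0.097). The number of genes changed in WT was 1503 without mRNA 20 °C replicate 2, 1486 without mRNA 37 °C replicate 1, 1426 without footprint 20 °C replicate 1 and 1246 without footprint 37 °C replicate 3, and 1325 and 1534 with only the compared groups and without the 6 doubted libraries. In the mutant it was 1638 without mRNA 37 °C replicate 3 and 1646 without footprint 37 °C replicate 3.

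**Figure D3:**
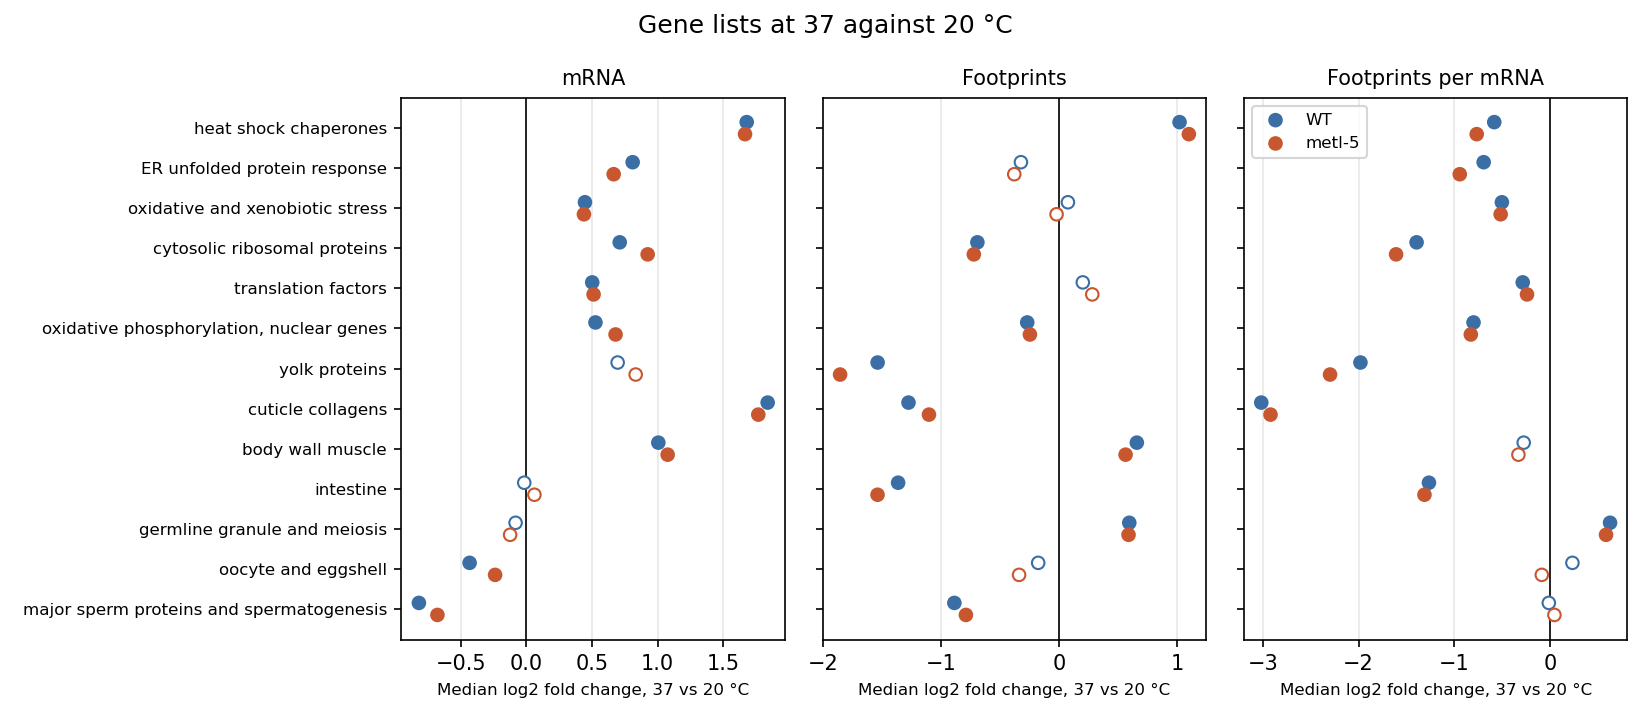
Median log2 fold change at 37 against 20 °C of gene lists in mRNA, footprints and translational efficiency, by strain; open symbols mark lists with a camera adjusted p of 0.05 or more. Cuticle collagens lie at 1.84 (WT) and 1.77 (mutant) in mRNA and at −3.01 and −2.92 in translational efficiency, while heat shock chaperones are above 0 in mRNA and footprints and below 0 in translational efficiency.

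Whether the strain changes the response to heat was tested as an interaction. For cyp-29A3 the heat response of mRNA differed between strains by 1.74 ± 0.815 and for metl-5 by 0.67 ± 0.539 (adjusted p = 1 for each), and for footprints by 3.46 ± 0.989 and 1.55 ± 0.733. Without the 6 doubted libraries the footprint value of cyp-29A3 was −0.451, with 1 count in the mutant at 37 °C. With edgeR 0 genes were called for mRNA (92 at an unadjusted p under 0.05), 0 for footprints (62) and 0 for translational efficiency (79), and DESeq2 also called 0 in each. The unadjusted counts are again below a share of 0.05 of the genes tested, so the edgeR test may be too strict. On simulated counts the interaction recovered 36, 27 and 11% of 4-fold changes in mRNA, footprints and translational efficiency. Of 2-fold changes it recovered 2, 0 and 0%, so these counts of 0 do not exclude changes of such size. Without footprint metl-5 37 °C replicate 1 edgeR called 1 gene for footprints, ZK228.3. Gene lists that camera called in the interaction, in which 0 single members were called, are given with the closing observations.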

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

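Every test of an explanation in this part was chosen only after the result it concerns was seen; the interaction tests of gene lists were planned.

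Camera called 13 interaction tests, each of a gene list in 1 assay or in translational efficiency (adjusted p under 0.05), although 0 single members were called. With an estimated correlation 0 of them were called (adjusted p = 0.995 for mRNA, 0.979 for footprints and 0.998 for translational efficiency). The ribosomal protein, proteasome and oocyte lists were each called in mRNA and in translational efficiency, which share the mRNA counts. A positive median means a larger rise or smaller fall in the mutant. In mRNA the medians were 0.2191 for 75 cytosolic ribosomal proteins (adjusted p = 1.48e-07), 0.1228 for mitochondrial ribosomal proteins (0.000175), 0.2262 for rRNA and small RNA methyltransferases (0.0281), 0.1306 for the proteasome (0.0038), 0.1637 for oxidative phosphorylation (0.0019), 0.1954 for oocyte and eggshell genes (0.0024) and −0.3562 for the intracellular pathogen response (0.04). In footprints the sperm list had a median of 0.0055 and a mean of 0.0561 (0.0047). In translational efficiency the medians were −0.3 for fatty acid beta-oxidation (0.0283), −0.1991 for cytosolic ribosomal proteins (0.0283), −0.1405 for the proteasome (0.0283), −0.2748 for oocyte and eggshell genes (0.0036) and 0.2966 for hypodermis and seam genes (0.0283). Without the 6 doubted libraries the translational efficiency calls of all but the proteasome were lost (hypodermis −0.283, oocyte 0.103, ribosomal proteins 0.003, beta-oxidation −0.241). Without the 2 libraries absent from the authors' tables all but hypodermis were lost (oocyte 0.179, ribosomal proteins 0.054, beta-oxidation −0.096, proteasome −0.049), and with the library pair as a block ribosomal proteins were (−0.158, adjusted p = 0.285). Without a filter on low counts 4 calls were lost: methyltransferases and pathogen response in mRNA (adjusted p = 0.0736 and 0.441), the sperm list in footprints (0.186) and hypodermis in translational efficiency (0.199). Each of these lists was lost in at least 1 fit that left out 1 library. For the ribosomal proteins these were, in mRNA, the fits without mutant 20 °C replicate 2 (0.079, adjusted p = 0.14) and without WT 37 °C replicate 2 (0.008, adjusted p = 0.906).

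A first pattern is that 4 footprint libraries hold reads of both strains and 2 others stand between the temperatures. A swap of labels would leave no library with both strains' markers, and 4 libraries hold them. Reads of the other temperature mixed in may account for metl-5 20 °C replicate 2 and WT 37 °C replicate 2. In the first, genes higher at 37 °C stood at a median of 32.1% of the way from their 20 °C to their 37 °C level (quartiles 25.7 and 34.7, 29 genes). Genes lower at 37 °C stood at 28.8% of that way (15.4 and 42.7, 421 genes). In the second, a library labelled 37 °C, the same measure gave 36.5% (28.2 and 64.1) and 52.5% (38.1 and 64.5). There it is the share of the library's own temperature, and the rest would be that of 20 °C. Both levels were taken from the undoubted libraries of the strain. A heat response of the worms of metl-5 20 °C replicate 2 stays open. The hsp-70 mRNA of that number was at 10.79 CPM (4.416 to 10.56 in the other 20 °C mRNA libraries), and nothing says that both libraries came from the same worms.

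A second pattern is the set of genes lower in the mutant besides metl-5: ZK228.3, ZK228.4, F56A4.3, cyp-29A3 and R13H9.6. In the main mRNA fit cyp-29A3 and R13H9.6 were called on average over temperatures only. DESeq2 also called cyp-29A3 at 20 °C and R13H9.6 at 37 °C (adjusted p = 5.52e-05 and 0.0355). A deletion reaching neighbours of metl-5 is argued against, since 0 of these 5 genes lie on chromosome III. ZK228.3 and ZK228.4 lie close together on chromosome V (18458241 to 18461250 and 18462787 to 18465426). The gene cTel55X.1 went the other way, with 0 mRNA counts in WT and 618 and 502 in the mutant at 20 and 37 °C. Each mutant library at 37 °C held 18 or more cyp-29A3 mRNA counts. These do not decide whether the gene is deleted, since the deleted metl-5 also kept 36 to 56 mRNA counts in each mutant library. A change in cyp-29A3 translation alone is argued against by its mRNA, at −3.87 on the log2 scale at 20 °C. Whether these genes depend on metl-5 or on another difference between the strains cannot be told apart with 1 mutant strain, and the effect of metl-5 is not tested apart from it.

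Another pattern is the low translational efficiency of cuticle collagens at 37 °C in WT. Without the 6 doubted libraries the median was −3.281. That fit keeps only replicate 1 of the WT 37 °C footprints, in which 34.8% of all reads were unmapped, so it does not decide on mixed footprint libraries. A trend with gene length and abundance is argued against by a median residual of −2.47 from a trend fitted on other genes (quartiles −3.306 and −1.654, 130 of 130 collagens). Library scaling is argued against, since a factor per library moves all genes alike and the collagens had a median of −2.996 relative to all other genes (quartiles −3.562 and −2.287). A change in translation of collagens in the heat stays open as a hypothesis, found and tested on the same libraries, as do other causes such as RNA that ribosomes cannot reach, which were not tested.

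Other splits of the same libraries were counted. Between 3 and 3 libraries only 10 splits exist, too few for a share under 0.05. For mRNA, the real and highest other counts were 4 and 510 between strains at 20 °C, 4 and 14 at 37 °C, 2432 and 0 for heat in WT, and 2660 and 0 for heat in the mutant. For footprints they were 0 and 0, 0 and 618, 2071 and 0, and 3332 and 0, and for translational efficiency 0 and 0, 0 and 39, 2335 and 0, and 2528 and 0. As many genes as in the real split were called in 2 of 10 splits for mRNA between strains at each temperature, in 10 of 10 for footprints and translational efficiency between strains, and in 1 of 10 for heat. The mRNA split with 510 calls set mutant 20 °C replicates 1 and 2 and WT 20 °C replicate 2 against the rest, and the footprint split with 618 set mutant 37 °C replicates 1 and 3 and WT 37 °C replicate 3 against the rest, which points to a structure of the samples other than the strain. Where the numbers pair the libraries, the real split parts all 3 pairs, and the 3 other splits that do so called 0 genes in each such comparison. The splits with 510, 14, 618 and 39 calls each part 1 pair and keep 2 pairs together, so they differ by replicate number.

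For tests over both temperatures 40 splits were drawn. For mRNA averaged over temperatures 1 split, the real one, gave 10 genes and the highest other gave 1, a share of splits under 0.05. The share cannot fall below 1 of 40 here, so chance is not excluded. Of the 32 splits that part all pairs of same-numbered libraries at both temperatures, again only the real one gave 10 genes, and the highest other gave 0. For the footprint and translational efficiency averages all 40 splits gave at least the real count of 0, with highest others of 4 and 0. For the interactions all 40 did as well, with highest others of 1184 for mRNA, 0 for footprints and 0 for translational efficiency. The 1184 calls of one split of mRNA also point to a structure of the samples.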

How the results depend on the processing

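The alternatives without 2 or 6 footprint libraries and with unstranded footprint counts were chosen after seeing the data, and the others were planned. Each was run, but lists were not tested with DESeq2 or limma, and the averages and interactions have no fit of compared groups only. Counts of calls stayed within 1.5 times the main count in 99 of 126 fits, and in 164 of 192 fits that left out 1 library. Here 0 calls in both fits were taken as kept, so these shares include many comparisons without any call. The footprint calls for heat in WT ranged from 0 to 4931 with 1 library left out. Gene values kept direction and side of the threshold in 1607 of 1689 fits and lists in 577 of 697, and an estimated correlation alone ended 101 of 103 list calls. With 1 library left out this held for 1763 of 2022 gene values and 818 of 930 list values. Where a value below moved, the cause was not tested, unless the fit itself had fewer libraries. Depth limits what can be called: footprint libraries held 4410194 to 19012050 gene counts, and 3 counts came to 0.680 CPM in the smallest.

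With the Wald test of DESeq2 the calls between strains at 20 and 37 °C were 8 and 7 in mRNA (4 and 4 in edgeR), 3 at 20 °C and 3 averaged in footprints (0 and 0), and 1, 3 and 1 at 20 °C, at 37 °C and averaged in translational efficiency (0 each), and footprints had 3277 for heat in WT (2071). Translational efficiency of metl-5 under heat in WT turned to 0.047, and to 0.044 with DESeq2 size factors in edgeR. Without a filter on low counts 7 genes were called in mRNA at 20 °C, 2 in footprints at 20 °C and 1 averaged, and metl-5 in translational efficiency at 20 °C was −0.007. With limma on paired differences translational efficiency had 1 call at 37 °C and 2 averaged, metl-5 was −0.058 at 20 °C, and cyp-29A3 was −0.463 under heat in the mutant and −0.181 averaged. With unstranded footprint counts metl-5 was −0.001 in translational efficiency at 20 °C.

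With the replicate number as a block mRNA at 20 °C had 8 calls, and footprints 3872 for heat in WT, where cyp-29A3 turned to −0.017. With the library pair as a block translational efficiency had 1 call at 20 °C and 1 averaged, and metl-5 was −0.069 at 20 °C and 0.008 under heat in WT, cyp-29A3 −0.042 under heat in the mutant. Besides these counts and the genes and lists named with a block value in their comparisons, the block changed no other call reported here. For mRNA between temperatures the numbers do not pair the libraries: 4 of 6 libraries in WT and 3 of 6 in the mutant deviated most like the library of their own number, and with the number as a block the calls were 3947 and 4054 (2432 and 2660 without it).

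With only the compared groups in the fit footprints had 2 calls at 20 °C and 118 for heat in WT, translational efficiency had 1325 for heat in WT (2335), and metl-5 in translational efficiency was −0.003 at 20 °C and 0.035 under heat in WT.

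Without the 2 footprint libraries absent from the authors' tables, footprints between strains at 20 °C turned to −0.574 for hsp-70, −0.619 for hsp-16.2, −0.431 for hsp-16.41 and −0.003 for the heat shock list. For heat in WT footprints had 4795 calls and cyp-29A3 was −0.137. In translational efficiency metl-5 was −0.536 at 20 °C, cyp-29A3 −0.098 under heat in the mutant, and the oocyte list 0.179 in the interaction. Leaving out the 6 doubted libraries left 1 library in each footprint group at 37 °C, assumed to vary like the other groups. Footprints then had 3 calls at 20 °C, 3 at 37 °C and 4 averaged, and hsp-70, hsp-16.2 and hsp-16.41 were −0.472, −0.501 and −0.291 at 20 °C. Footprints of metl-5 were −0.028 under heat in WT, and of cyp-29A3 −0.449 under heat in the mutant and −0.451 in the interaction. Translational efficiency had 1534 calls for heat in WT. For metl-5 it was −0.7 at 20 °C, −1.024 at 37 °C, −0.52 under heat in the mutant, −0.324 in the interaction and −0.862 averaged. For cyp-29A3 it was −2.771 at 37 °C, −3.837 under heat in the mutant, −2.172 in the interaction and −1.685 averaged. All cyp-29A3 values of this fit rest on 1 footprint count in the mutant at 37 °C.

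With 1 library left out, mRNA had 1175 to 2988 calls for heat in WT, 1263 to 2509 in the mutant and 6 to 9 averaged between strains. Footprints had 0 to 4931 for heat in WT, 0 to 3348 in the mutant, 0 to 1 in the interaction and 0 to 2 averaged. Translational efficiency had 1246 to 3283, 1638 to 2770, and 0 to 2 between strains at 37 °C.

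The following values turned direction in at least 1 such fit. In mRNA these were metl-5 under heat in WT (−0.019 to 0.428) and the collagen list between strains at 20 °C (−0.694 to 0.229) and 37 °C (−0.805 to −0.063). In footprints at 20 °C these were hsp-70 (−0.562 to 6.38), hsp-16.2 (−0.613 to 6.645), hsp-16.41 (−0.422 to 7.014), the heat shock list (0.008 to 0.22) and the collagens (−0.6 to 0.145), then cyp-29A3 under heat in WT (−0.148 to 0.339) and the sperm list in the interaction (−0.164 to 0.438). In translational efficiency these were metl-5 at 20 °C (−0.537 to 0.284) and under heat in WT (−0.226 to 0.241), cyp-29A3 under heat in the mutant (−0.956 to 0.62) and averaged (−0.259 to 0.543), and in the interaction ribosomal proteins (−0.434 to 0.165) and oocyte genes (−0.695 to 0.06). A list can turn by its mean while its median keeps its sign.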

Other observations

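The list tests in this part were planned, and the comparison of mRNA with footprints across genes was chosen only after the heat results were seen.

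Several gene lists that the report leaves out moved with heat in mRNA, each by camera with the preset correlation only. Of 47 nuclear genes of oxidative phosphorylation 12 were higher in WT and 20 in the mutant, with 0 lower (12 and 26 higher adjusted over the list alone). Their medians were 0.53 and 0.68 (camera adjusted p = 1.63e-06 and 1.29e-09, adjusted p = 0.472 and 0.425 with an estimated correlation), with ucr-2.1 up by 1.5 ± 0.279 and 1.7 ± 0.28. Of 31 proteasome genes 4 and 9 were higher and 0 lower (3 and 12 higher adjusted over the list alone; 0.000142 and 5.87e-07, adjusted p = 0.630 and 0.425 with an estimated correlation). Among them rpn-3 rose by 0.872 ± 0.215 and 1.005 ± 0.216. Of 25 hypodermis and seam genes 14 and 12 were higher and 2 lower in each strain (18 and 15 higher, 3 and 3 lower adjusted over the list alone; 2.51e-05 and 0.0012, adjusted p = 0.472 and 0.425 with an estimated correlation), with medians of 1.73 and 1.62. This list holds collagens such as col-10, which rose by 3.13 ± 0.476 and 3.29 ± 0.48. Of 29 targets of insulin signalling 8 and 9 were higher and 2 lower in each strain (9 higher and 2 lower in each adjusted over the list alone; 0.0059 and 0.0038, adjusted p = 0.156 and 0.121 with an estimated correlation). The list shares heat shock genes with the chaperone list, while lea-1, which is not among those, rose by 1.78 ± 0.241 and 1.77 ± 0.241.

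The proteasome and hypodermis lists were called lower in translational efficiency by camera, although few proteasome members were in WT. Of 31 proteasome genes 2 fell in WT and 11 in the mutant, with 0 higher (1 and 13 lower adjusted over the list alone), and the medians were −0.58 and −0.74 (8.72e-05 and 3.93e-07, adjusted p = 0.593 and 0.473 with an estimated correlation). The gene rpn-2 fell by 1.25 ± 0.308 and 1.47 ± 0.309. Of 25 hypodermis and seam genes 13 and 10 fell and 2 rose in each strain (17 and 11 lower, 2 and 2 higher adjusted over the list alone; 6.89e-06 and 0.0016, adjusted p = 0.383 and 0.473 with an estimated correlation), with col-19 at −3.38 ± 0.655 and −3.68 ± 0.658. In footprints, 4 and 6 of 35 ribosome biogenesis genes were higher and 0 and 1 lower (4 and 6 higher, 0 and 1 lower adjusted over the list alone; 0.0016 and 0.0011, adjusted p = 0.707 and 0.763 with an estimated correlation), with rpoa-12 up by 1.36 ± 0.294 and 1.39 ± 0.294. Of 13 rRNA and small RNA methyltransferase genes 4 were higher in each strain and 0 and 1 lower (7 and 8 higher, 0 and 2 lower adjusted over the list alone; 0.0072 and 0.0086, adjusted p = 0.707 and 0.763 with an estimated correlation), with metl-2 up by 0.79 ± 0.216 and 1.1 ± 0.218. Of 27 genes of fatty acid synthesis 6 and 10 had lower footprints and 1 higher (11 and 10 lower, 1 and 1 higher adjusted over the list alone; 0.000163 and 0.000566, adjusted p = 0.707 and 0.763 with an estimated correlation), with fasn-1 at −1.29 ± 0.346 and −1.69 ± 0.35.

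Across 12079 genes the heat responses of mRNA and footprints had r = 0.355 in WT and 0.362 in the mutant. Of these genes 1.99% in WT and 2.19% in the mutant were called higher in both, and 1.36% and 2.96% lower in both. Higher mRNA went with lower footprints in 0.687% and 1.49%, and lower mRNA with higher footprints in 1.29% and 1.47%. What independent lists would share was not computed here, so these shares alone do not show opposite regulation.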
